A study of Saccharomyces cerevisiae with 8 samples.

How the data were processed

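The series measured where 4 proteins of the RNA polymerase III (Pol III) machinery sit on the genome of budding yeast, Saccharomyces cerevisiae, by chromatin immunoprecipitation followed by hybridisation to arrays of intergenic regions. Brf1 and Bdp1 are subunits of TFIIIB, the factor that recruits the polymerase. Tau95 is a subunit of TFIIIC, the factor that binds the internal promoter of tRNA genes, and C160 is the largest subunit of the polymerase. Bdp1, Brf1 and Tau95 carried a myc epitope and C160 an HA epitope, per the labels. Each protein was measured in exponential growth in rich medium, either untreated (0 min) or after 30 min with rapamycin at 0.2 ng per µl. Rapamycin inhibits the TOR kinase complex 1 and so mimics starvation for nutrients. This gives 8 groups of 1 deposited sample each, called arrays here, and each may summarise several hybridisations. Every array has 2 channels: per the labels, Cy5 carried immunoprecipitated DNA of the wild type and Cy3 that of a strain lacking MAF1, the gene of the general repressor of Pol III.

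The deposited table holds 1 log2 value per feature and array. Per the labels' design text, the experiments were done in triplicate, and enrichment ratios of the replicates were scaled so that a list of loci not bound by the Pol III machinery had a median of 1, which is 0 on a log scale. The list itself was not used here. Background correction, spot filters and the array platform's processing are not given in the sources used here. Replicate values were not used here either, so the replicates' spread is unknown, no value carries a replicate error and no p-value was computed. For arrays, their number alone limits the precision.

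The scale and the kind of value were worked out from the numbers. On the Brf1 array at 30 min, 93.9% of the 2873 antilogs of base 2 below the median lay within 0.05 steps of a whole multiple of 1/157, where chance gives 10%. The strength of such steps on this array was 0.94 for base 2, 0.25 for base e and 0.27 for base 10. On the other arrays base 2 was also the strongest but weak, at 0.16 to 0.32, except on the Tau95 array at 30 min. There no base stood out, at 0.050, 0.051 and 0.056 for base 2, e and 10. Base 2 was taken for all arrays. The region named for the 35S ribosomal RNA genes, which are repeated many times, ranked between 1 and 12 among all features on the 6 arrays that gave it a value. All 28 pairs of arrays correlated across features, with Pearson's r between 0.81 and 0.96. A ratio of wild type to mutant would remove what both strains share, while here the Pol III class stood between 2.01 and 3.27 on every array, so the values were read as a relative brightness of immunoprecipitated DNA. Which channel, and so which strain, gave the values stays unknown, as does the reference they were divided by. The design fixed beforehand assumed a ratio of wild type to mutant. Its summaries were kept, applied to these values, and no statement on the MAF1 deletion was made. The feature named for MAF1 stands, by its name, for the region beside the gene. The limits of the deletion are not given in the sources used here, so this feature was not used to check the strains.

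The medians of all features lay between -0.08 and 0.17. Values were missing for 117 to 639 of the 6399 features per array. The Brf1 array at 30 min lacked the most and was dim, as its steps of 1/157 show. The Tau95 array at 30 min lacked 6 of the 32 features whose mean on the other arrays was 5 or more, and its highest value was 5.61 where the other arrays reached between 6.81 and 8.13.

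A feature's name is the letter i followed by a gene, tRNA gene or other element. A test on the arrays showed that it stands for the intergenic region on the side of higher coordinates. Features of genes with a tRNA gene next on that side had a median of 2.91 on the Bdp1 array at 0 min (n = 209), and those with one on the other side 0.14 (n = 192). Gene symbols and neighbours came from a table of RefSeq genes of assembly R64, which matched 5525 of 5806 features named for open reading frames. The build of the array is not given in the sources used here, so no coordinates are printed. Pol III features are the 250 named for nuclear tRNA genes (243 distinct genes) and 7 named for other Pol III genes, 257 in all. A name pattern for tRNA suppressors also took protein-coding genes, which were removed. The remaining 6142 are called other features. Many of these flank a tRNA gene and are no clean background, so a stricter pool without them and without features of long terminal repeats was used for matched lists.

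For each array the median, quartiles and number of features past 2-fold (a log2 value of 1 in size) were computed for both classes. The change is the value at 30 min minus that at 0 min on the 2 arrays of a protein. Differences between proteins are medians over features of the difference of their changes, for the 6 pairs. A list's median was set against the medians of 10000 random lists of equal size from the other features, and against lists matched on level in 10 bins. These percentiles describe these arrays and are not tests of the treatment. The 95% intervals of medians come from order statistics (exact binomial) and cover the spread over features only. The procedure was tested on simulated data with 200 shifted features per protein: the shift was recovered within 0.073 for each of the 4 proteins. With a simulated compression of bright features, level matching left an error of 0.09 for Brf1 and no matching 0.24. The simulated features were drawn from the brighter other features and matched, in the wide pool, on the very value that set the compression. Pol III features are brighter, and for them the stricter pool is thinner. The simulation therefore does not show how well matching removes compression there.

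Lists fixed before the data were examined were other Pol III genes, nuclear tRNA genes, ribosomal DNA of Pol I, small nuclear and nucleolar RNA genes of Pol II, ribosomal protein genes, ribosome biogenesis genes, glycolytic and other highly transcribed genes, nitrogen-regulated genes, stress genes, the tagged genes, marker genes and genes of the Pol III machinery. Lists of mitochondrial tRNA genes and of sites bound by TFIIIC alone matched no feature by name, nor did ZOD1 and RNA170. Named features followed a rule fixed beforehand: all measured Pol III genes other than tRNA genes, MAF1, the 4 tRNA features with the lowest and the 4 with the highest change per protein, the 3 other features at either end, and the 2 members of each list with the largest mean size of change. The tRNA and other features at either end had to have a value on all 8 arrays. Features outside this rule are said to be chosen after their values were seen.

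Alternatives concerned the zero point, the summary over features, the features counted, the spread of the arrays, the limit and the random lists. Turning the sign and another log base were planned for a ratio of unknown direction or base. They were not run, because the values were read as a brightness and not as such a ratio, and the same base was taken for all arrays. That base was assumed, not settled, on the Tau95 array with rapamycin, where no base stood out. The effect of another base there was not tested. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.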

Results

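Occupancy of the genome by 4 proteins of the Pol III machinery was measured in yeast before and after 30 min of rapamycin, in 8 deposited samples, called arrays here, with 1 per protein and time. The deposited value of a feature was read as a relative brightness on the log2 scale. Neither the strain behind it nor what it was divided by is known, and per the labels its zero is the median of loci that the machinery does not bind. Values were given for 5760 to 6282 of the 6399 intergenic features per array. No replicate values were used here, so every difference is without a replicate check and is described by its size, its spread over features and its place among random lists. The feature named for MAF1, the repressor whose deletion strain was on the arrays, stands for the region beside the gene and checks nothing about the strains, since the limits of the deletion are unknown. Its value was -0.54 for Bdp1, 0.18 for Brf1, 0.17 for C160 and 0.62 for Tau95 at 0 min. At 30 min it was 0.16, 1.88, 0.65 and 0.22.

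The first question was where the 4 proteins sat in growing cells. Before rapamycin, the features of tRNA and other Pol III genes were far brighter than the rest on all 4 arrays. Their median was 3.27 for Bdp1 (quartiles 2.13 and 4.24, n = 251), 3.06 for Brf1 (2.24 and 3.89, n = 252), 2.95 for C160 (1.89 and 3.86, n = 252) and 2.01 for Tau95 (1.08 and 2.93, n = 252). Other features had medians of 0.01, -0.05, -0.12 and 0.00. A value of 1 or more was found at 220 Pol III features for Bdp1, 232 for Brf1, 220 for C160 and 192 for Tau95. Among other features, 1515, 1190, 1217 and 1436 reached it. Regions beside an open reading frame whose next gene is a tRNA gene, chosen for this after the data were seen, had medians of 2.91, 2.66, 2.41 and 1.72. On each array the Pol III median lay above all 10000 random lists. What besides occupancy sets the brightness of a feature was not measured.

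The values of single Pol III features are given here as brightness, and since effects of the probe and of copy number were not removed, they do not rank the genes by occupancy. The feature of tM(CAU)D, a methionine tRNA gene (the letters give amino acid, anticodon and chromosome), had 5.16 for Bdp1, 4.97 for Brf1, 5.08 for C160 and 3.33 for Tau95. The region of SNR6, which encodes the U6 spliceosomal RNA, had 5.17, 4.02, 4.53 and 3.23. RPR1, the RNA of RNase P, had 2.42, 3.15, 3.17 and 2.57, and SCR1, the RNA of the signal recognition particle, had 1.88, 1.998, 3.22 and 1.11. RDN5-1, a 5S ribosomal RNA gene present in many copies, reached 5.98, 6.27, 6.15 and 5.46. The feature named for SNR52, a snoRNA gene of Pol III, was dim, at -0.86 for Brf1, -1.60 for C160 and -1.20 for Tau95. The region to the left of SNR52, beside PMD1, was brighter, at 2.83, 0.60, 1.30 and 2.12 for Bdp1, Brf1, C160 and Tau95, and it was chosen after the values were seen. RDN5-3 was near zero at -0.13, 0.11, -0.09 and -0.31.

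After 30 min of rapamycin the Pol III features were still the bright class on all 4 arrays. Their median was 2.95 for Bdp1 (quartiles 1.80 and 4.10, n = 251), 2.32 for Brf1 (1.33 and 3.26, n = 248), 2.45 for C160 (1.43 and 3.40, n = 252) and 2.32 for Tau95 (1.34 and 3.20, n = 251). Other features had medians of 0.03, 0.04, -0.05 and 0.11. Values of 1 or more were found at 217, 206, 214 and 214 Pol III features, and at 1562, 1393, 1374 and 1532 other features. Each Pol III median again lay above all 10000 random lists.

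**Figure D1:**
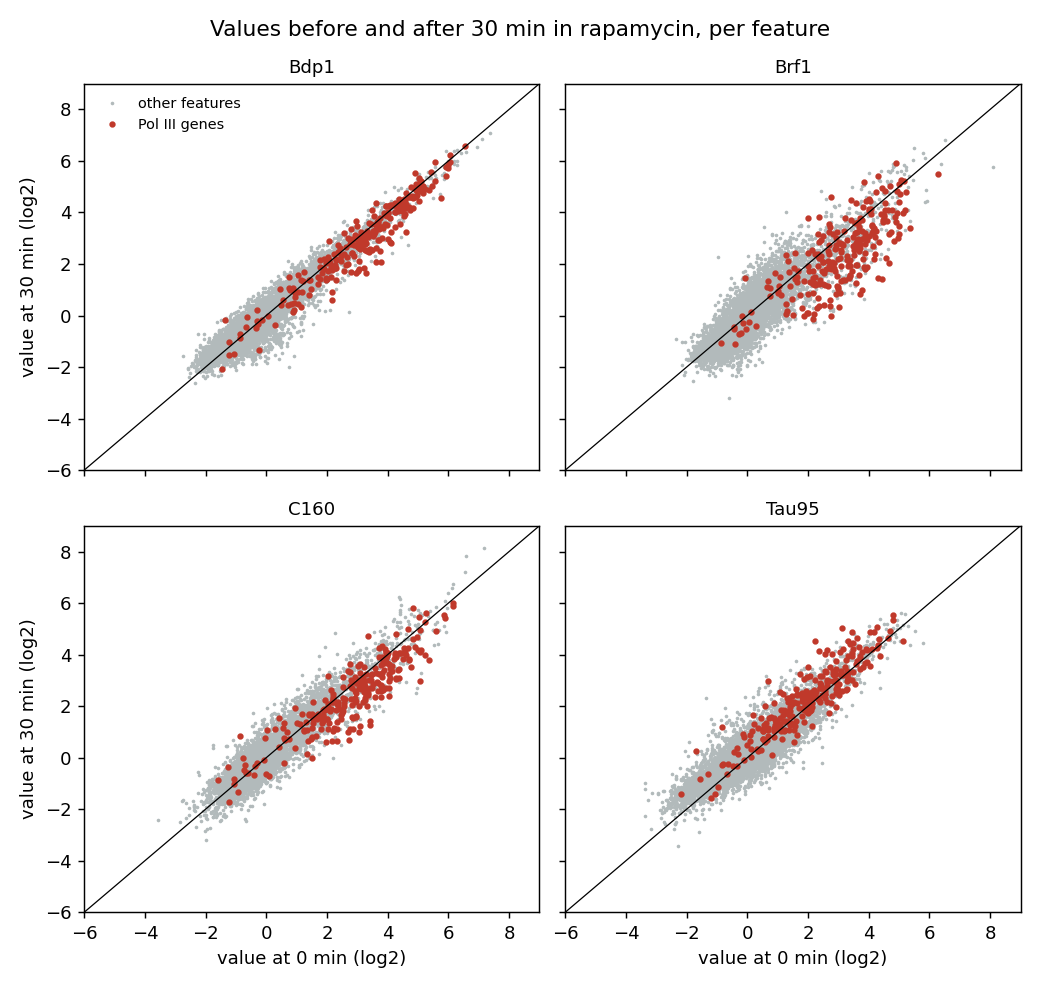
Deposited log2 values at 0 min (horizontal axis) and 30 min of rapamycin (vertical axis), 1 point per feature and 1 panel per protein, with Pol III genes in red, other features in grey and the line of equal values in black. For Bdp1, Brf1 and C160 most red points lie under the line, with median changes of -0.20, -0.70 and -0.32. For Tau95 most lie above it, with a median change of 0.27.

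The next question was whether rapamycin alters the presence of the polymerase on its genes. For C160 the Pol III features were lower at 30 min, by a median change of -0.32 (quartiles -0.78 and 0.02, n = 252), a ratio of 0.803, while other features had a median change of 0.10. A change of 2-fold or more was found downward at 41 Pol III features and upward at 5. Of 6006 other features, 95 were lower and 205 higher by this limit, or 132 and 160 with arrays centred on all features. The histidine tRNA gene tH(GUG)E1 had the lowest change at -2.14, followed by tM(CAU)D at -2.11, tR(UCU)E at -2.05 and tK(CUU)D1 at -2.05. At the other end were tP(AGG)N at 1.73, tL(CAA)N at 1.35, tK(CUU)I at 1.12 and tV(CAC)H at 1.11. The lowest changes among other features were those of the regions beside GCD11 (-2.41), CLB6 (-2.28) and GMC1 (-2.21), and in the gene table the next gene of each is a tRNA gene. The highest were beside FYV10 (2.58), TRM10 (2.37) and KAP123 (2.20). The Pol III median lay below all 10000 random lists, and the change was -0.65 when the arrays were scaled to equal spread of the other features.

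For Brf1, the TFIIIB subunit that carries the contact to the polymerase, the change was the largest of the 4 proteins. The Pol III median was -0.70 (quartiles -1.24 and -0.06, n = 248), a ratio of 0.615, against -0.01 for other features. A 2-fold lower value was found at 81 Pol III features and a 2-fold higher one at 9. Other features went both ways, 328 down and 295 up of 5511, or 428 and 230 with arrays centred on all features. The isoleucine tRNA gene tI(AAU)I1 went from 4.44 to 1.41, a change of -3.04. It was followed by the glycine gene tG(GCC)J1 at -2.88, the serine gene tS(AGA)D1 at -2.85 and the lysine gene tK(CUU)G2 at -2.81. Higher at 30 min were tW(CCA)M by 1.87, tP(AGG)N by 1.54, tV(CAC)H by 1.49 and tK(CUU)J by 1.33. Beside RAD30, whose next gene is a tRNA gene, the change was -3.19, beside AUS1, also next to a tRNA gene, it was -2.87, and beside YCL022C -2.78. The regions of RET3 (3.24), POR1 (2.89), also next to a tRNA gene, and ECL1 (2.75) had the highest changes. The Pol III median was below all 10000 random lists. This array at 30 min was dim and lacked 639 features. With equal spread of the other features the median change was -1.46. That spread was 1.00 at 0 min and 1.27 at 30 min, so the scaling widens the fall by construction. It does not correct for the dimness.

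Bdp1, the other TFIIIB subunit measured, had a smaller change. The Pol III median was -0.20 (quartiles -0.46 and 0.06, n = 251), a ratio of 0.871, against 0.05 for other features. A 2-fold lower value was found at 17 Pol III features and a higher one at 1, tW(CCA)K, with 1.18. Of 5670 other features, 144 were lower and 45 higher. The phenylalanine genes tF(GAA)G (-1.72) and tF(GAA)M (-1.56), the glutamine gene tQ(UUG)D1 (-1.64) and the serine gene tS(AGA)D1 (-1.56) had the lowest changes. After tW(CCA)K, the highest were tV(UAC)B at 0.85, tE(UUC)B at 0.75 and tP(UGG)L at 0.74. Among other features the lowest were beside MYO5 (-2.74), a long terminal repeat named YELWDELTA5 (-2.61) and YPS1 (-2.11). The highest were beside YKL097C (1.52), MNN2 (1.40) and ANB1 (1.39). The Pol III median was below all 10000 random lists, and it was -0.34 with arrays centred on ribosomal protein genes. The median of those genes itself went from -0.08 to 0.07 for Bdp1, which sets this shift.

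For Tau95, in TFIIIC, the Pol III features were higher at 30 min, by a median of 0.27 (quartiles -0.06 and 0.68, n = 251), a ratio of 1.21. Other features also had a positive median change, 0.19, so that the difference between the classes was 0.09, and the change was 0.15 with arrays centred on all features. A 2-fold higher value was found at 30 Pol III features and a lower one at 0 of 251, or 20 and 3 with that centring. Other features had 399 higher and 113 lower of 5990, or 289 and 180. The leucine gene tL(CAA)G2 and the tyrosine gene tY(GUA)F2 were highest, at 2.29 each, with tP(UGG)F at 2.04 and tV(AAC)L at 1.96. The lowest were tV(AAC)G2 (-0.96), tM(CAU)P (-0.96), tI(AAU)E2 (-0.92) and tS(AGA)D3 (-0.88). Beside XYL2 (3.70), BRR2 (2.72) and LOG1 (2.67) the changes were the highest of the other features, and beside UBC4 (-2.66), MSN2 (-2.21) and BER1 (-2.04) the lowest. The Pol III median stood at the 97.8th percentile of random lists. Against lists matched on the value at 0 min, it lay above all 10000. The change was 0.54 with equal spread of the other features and 0.46 with arrays centred on ribosomal protein genes. The median of those genes itself went from 0.28 to 0.09 for Tau95, and centring on it adds that fall to the Pol III change.

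**Figure D2:**
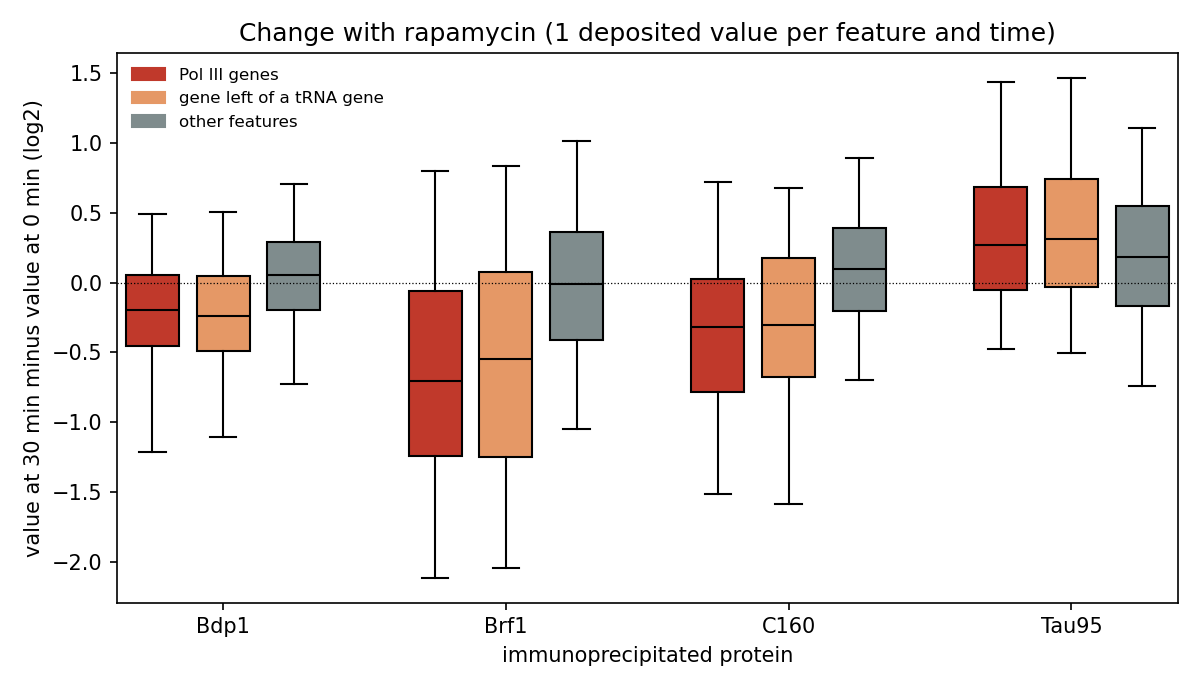
Change of the log2 value from 0 to 30 min of rapamycin for each immunoprecipitated protein, as boxes (quartiles, with the median as a line and whiskers from the 5th to the 95th percentile) over Pol III features, regions left of a tRNA gene and other features (which include those regions), with 1 deposited value per feature and time. The Pol III medians are -0.20 for Bdp1, -0.70 for Brf1, -0.32 for C160 and 0.27 for Tau95.

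Comparing the proteins addresses whether polymerase, TFIIIB and TFIIIC behave alike. At the same Pol III features, the change of Brf1 was below that of Tau95 by a median of -0.99 (n = 247), that of C160 below Tau95 by -0.65 (n = 251) and that of Bdp1 below Tau95 by -0.57 (n = 250). Other features had -0.22, -0.08 and -0.14 for these pairs. Within TFIIIB, the change of Bdp1 minus that of Brf1 was 0.42 (n = 247), against 0.04 for other features. Bdp1 minus C160 was 0.16 (n = 251) and Brf1 minus C160 -0.33 (n = 248), against -0.06 and -0.13. All 6 medians lay outside the 10000 random lists, and none could be tested against replicates. Bdp1 minus C160 depended on the zero point, being 0.053 with arrays centred on ribosomal protein genes, and was 0.030 at regions left of a tRNA gene. With equal spread of the other features the gaps were wider, such as -2.03 for Brf1 minus Tau95, -1.18 for C160 minus Tau95 and 1.13 for Bdp1 minus Brf1. Brf1 minus C160 was then -0.80 and Bdp1 minus C160 0.35. Such scaling moves bright features by construction, so the wider gaps are no separate evidence.

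Of 246 Pol III features with all values, 116 (47.2%) were lower for C160, Brf1 and Bdp1 together, against 13.3% of 5241 other features. At 74 of these 116 Tau95 was higher as well, which is 30.1% of the 246, against 6.81%. Tau95 was lower at 72 of all 251 Pol III features with a change (28.7%), against 35.3% of other features. The gap to other features thus stems mainly from C160, Brf1 and Bdp1. It does not show that Tau95 rises where these fall. Across Pol III features the change of Tau95 correlated weakly and positively with that of Bdp1, Brf1 and C160, at 0.18, 0.23 and 0.28. Across other features these values were 0.08, 0.07 and 0.15. A 2-fold lower value for both C160 and Brf1 was found at 20 of the 246 (8.13%), against 0.59%. The arginine gene tR(UCU)G2 was such a case, with changes of -1.30 for Bdp1, -2.07 for Brf1, -1.98 for C160 and 1.24 for Tau95. The phenylalanine gene tF(GAA)G had -1.72, -1.95, -1.69 and -0.25. The valine gene tV(AAC)G2 was lower for all 4 proteins, at -1.21, -2.34, -1.36 and -0.96. The changes of protein pairs correlated weakly across Pol III features, with Pearson's r from 0.18 for Bdp1 and Tau95 to 0.37 for Brf1 and C160. Across other features the 6 values ran from 0.07 to 0.26. Genes on the same arrays are not independent replicates.

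Families of tRNA genes were compared to see whether an amino acid stands apart. Of 20 families, the median change was below zero in 20 for C160, 19 for Brf1, 17 for Bdp1 and 2 for Tau95. For C160 the lowest family was glutamate (-0.79, n = 16) and the highest methionine (-0.01, n = 10). For Brf1 they were asparagine (-1.37, n = 9) and histidine (0.06, n = 5). Bdp1 ranged from histidine (-0.46, n = 6) to tryptophan (0.16, n = 6), and Tau95 from asparagine (-0.08, n = 9) to tryptophan (0.71, n = 6). The spread of the family medians was ordinary among 2000 shuffles of genes over families, at the 74.6th, 53.3rd, 12.8th and 69.4th percentile for Bdp1, Brf1, C160 and Tau95.

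Pol III genes other than tRNA genes were compared as a list of their own. Their median change was -0.03 for Bdp1, 0.02 for Brf1, -0.09 for C160 and 0.50 for Tau95 (n = 6 or 7), at the 30.1st, 55.9th, 17.7th and 90.7th percentile. RDN5-3 and SNR52 were not bright at 0 min, nor was RDN5-2, at -0.65, 0.76, 0.03 and -0.10 for Bdp1, Brf1, C160 and Tau95. A loss could hardly show at such features, so these medians do not say that the genes keep their occupancy. SCR1 was higher for Brf1 by 1.77 and lower for C160 by -0.41. SNR6 had -0.14, 0.03, -0.29 and 0.54 for Bdp1, Brf1, C160 and Tau95, and RPR1 0.19, -0.40, -0.09 and 0.00. RDN5-1 had -0.27, -0.79 and -0.17 for the first 3 proteins and no value for Tau95 at 30 min. RDN5-2 was higher for C160 by 1.06 and for Tau95 by 0.92. RDN5-3 had -0.05, 0.02, -0.02 and 0.47, and SNR52 had -0.22 for Brf1, 0.72 for C160 and -0.36 for Tau95.

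Genes of the other polymerases and of nutrient responses served as background. Features of ribosomal protein genes had a median change of -0.22 for Tau95 (n = 127), below all 10000 random lists, and of -0.06 for Bdp1, -0.01 for Brf1 and 0.00 for C160, at the 0.21st, 51.9th and 1.23rd percentile. RPL31B had -1.58 and RPS17B -1.11 for Tau95. Glycolytic and other highly transcribed genes had -0.19 for Tau95 (n = 26, 0.06th percentile), with FBA1, an aldolase, at -2.01 and TDH3, a glyceraldehyde phosphate dehydrogenase, at -0.98. Against lists matched on the value at 0 min this list was at the 1.27th percentile. Their median was 0.24 for Bdp1 (98.8th percentile), 0.15 for Brf1 (89.1st) and -0.09 for C160 (3.42nd).

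Small nuclear and nucleolar RNA genes of Pol II had -0.27 for Brf1 (n = 35, 1.31st percentile), 0.04 for Bdp1, -0.04 for C160 and 0.00 for Tau95. Among them SNR67 had -2.19 for Brf1 and -1.41 for C160, and SNR47 had -1.85 for Tau95. Ribosome biogenesis genes had -0.04, -0.15, 0.12 and 0.27 for Bdp1, Brf1, C160 and Tau95, with NOP58 at 1.91 and RRP15, which lies next to a tRNA gene, at -1.67 for C160. Nitrogen-regulated genes had 0.08, 0.22, 0.11 and 0.32 in that order, with the 2 features of DLD3 at 1.70 and 1.77 for Tau95. Stress genes had 0.13, 0.06, 0.12 and 0.09, with GAC1 at 2.34 and HSP104, next to a tRNA gene, at -1.82 for Brf1. Genes of the Pol III machinery had 0.02, 0.27, 0.06 and 0.24, where RPC17, next to a tRNA gene, had -2.02 for C160 and MAF1 1.71 for Brf1. The features of the tagged genes (n = 3) had -0.13, 0.62, -0.01 and -0.16, with RPO31, the gene of C160, at 0.98 for Brf1 and BDP1 at 0.82 for C160. Those of marker genes (n = 4) had -0.03, 0.18, 0.05 and 0.35, with ADE2 at 0.86 and URA3 at 0.73 for Tau95. The single feature of the Pol I ribosomal DNA, RDN37-1, had -2.33 for Brf1 and 0.67 for C160, with no value for the change of Bdp1 and Tau95. With arrays centred on all features, the small medians of other Pol III genes for Brf1 (-0.08), of stress genes for Brf1 (-0.04) and Tau95 (-0.02), of marker genes for C160 (-0.03) and of genes of the Pol III machinery for C160 (-0.02) and Bdp1 (-0.0021) were negative.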

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

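The tests of level and of yield in this part were chosen after the results were seen, and that of the dim array after the data were seen but before its result. At Pol III features the change with rapamycin had opposite signs for Tau95 and for each of the other 3 proteins. Other features were also higher for Tau95, by a median of 0.19, so the gap between the classes was 0.09. The Pol III median for Tau95 stood at the 97.8th percentile of random lists, and above all lists matched on level. The median difference was -0.57 for Bdp1 minus Tau95, from medians of -0.20 and 0.27. It was -0.99 for Brf1 minus Tau95, with Brf1 at -0.70, and -0.65 for C160 minus Tau95, with C160 at -0.32. With 1 deposited value per feature and group these differences were not tested. The Tau95 array at 30 min lacked 6 of the 32 features whose mean on the other arrays was 5 or more. Its log base was assumed, and whether these limits affect the sign for Tau95 was not tested.

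The lower values of Brf1 and C160 at tRNA genes may be technical or follow from the treatment. A compression of bright features on the array at 30 min would lower other features of the same level too. Lists matched on mean level, away from Pol III genes, had higher medians: the Pol III median was below theirs by -0.94 for Brf1 and by -0.70 for C160, and below the lowest of 10000 lists in both cases. This pool is thin, with 12 and 16 features in its smallest bin. With the other ways of matching and the wider pool the differences ran from -0.49 to -0.83 for Brf1 and from -0.44 to -0.68 for C160, again below all lists. If the dim Brf1 array at 30 min acted through a floor at low values, it would matter least for bright features. Yet Pol III features with a mean value above 2 had a median change of -0.70, the same as all Pol III features. A floor would hold low values up rather than lower them, so this outcome says little about the dimness. A weak signal that would lower bright features too was not covered. A lower yield of the immunoprecipitation from treated cells cannot be told apart from the treatment, since each group has 1 deposited sample and the spread between its experiments is unknown. A loss of polymerase and Brf1 from tRNA genes in rapamycin, with TFIIIC left in place, stays open as a hypothesis beside it.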

How the results depend on the processing

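The zero points, summaries, limits and lists were chosen before the data were examined, while the regions left of a tRNA gene, the features with a mean value above 2 and the lists matched on mean level were added after seeing the data. The limit of 2 was set before its own result was computed. Of 552 recomputed medians, 6 turned sign, all of them small list medians with arrays centred on all features. They were other Pol III genes (Brf1, -0.08), stress genes (Brf1, -0.04, and Tau95, -0.02), marker genes (C160, -0.03) and genes of the Pol III machinery (Bdp1, -0.0021, and C160, -0.02). Of all values recomputed, 614 stayed within the interval or factor allowed, 85 moved, 4 list percentiles passed the 1st or 99th and 1 no longer did. Runs without the tRNA genes of 1 amino acid, which drop a small part of the features, made up much of these totals. They gave 80 values each for the levels at 0 min, the levels at 30 min and the changes, and 120 for the differences. All of these stayed. Such runs, and levels far above zero, could hardly turn sign, so the totals say little about robustness. Leaving out the tRNA genes of each amino acid in turn gave median changes from -0.23 to -0.18 for Bdp1, -0.73 to -0.68 for Brf1, -0.36 to -0.29 for C160 and 0.26 to 0.29 for Tau95. No paired analysis was possible because each group has 1 deposited value per feature and no result comes from a test, and for the same reason no replicate could be left out. The dimness of the Brf1 array at 30 min limits its low features. Where values moved, the cause was not tested unless the setting itself sets the value.

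With arrays scaled to equal spread of the other features, the median changes were -1.46 for Brf1, -0.65 for C160 and 0.54 for Tau95. This scaling stretches arrays with a narrow spread and shrinks those with a wide one, so it moves bright features by construction. The levels were 2.91 (Bdp1), 3.67 (Brf1) and 3.44 (C160) at 0 min and 2.55 (Bdp1) at 30 min. The differences were 1.13 for Bdp1 minus Brf1, 0.35 for Bdp1 minus C160, -0.79 for Bdp1 minus Tau95, -0.80 for Brf1 minus C160, -2.03 for Brf1 minus Tau95 and -1.18 for C160 minus Tau95. Centring on all features gave a Tau95 change of 0.15, list medians for Tau95 of 0.14 (tRNA genes), -0.12 (small nuclear and nucleolar RNA) and -0.33 (ribosomal protein), and 2-fold lower Tau95 values at 3 Pol III and 180 other features. Centring on ribosomal protein genes gave changes of -0.34 for Bdp1 and 0.46 for Tau95, a Tau95 level of 1.73 at 0 min, and differences of 0.053 (Bdp1 minus C160), -0.91 (Bdp1 minus Tau95), -1.20 (Brf1 minus Tau95) and -0.88 (C160 minus Tau95). The ribosomal protein genes themselves moved, their median going from 0.28 to 0.09 for Tau95 and from -0.08 to 0.07 for Bdp1. This zero point shifts the Pol III values by as much, so they are no independent estimates of a change. The mean in place of the median gave 2.77 for C160 at 0 min.

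Regions left of a tRNA gene had lower levels, at 2.91, 2.66, 2.41 and 1.72 at 0 min and 2.53, 1.94, 1.90 and 2.09 at 30 min for Bdp1, Brf1, C160 and Tau95. Their differences were 0.29 (Bdp1 minus Brf1), 0.030 (Bdp1 minus C160) and -0.66 (Bdp1 minus Tau95). Lists matched on mean level put the Pol III change of Tau95 at percentile 100. Lists matched at 0 min put the tRNA genes at 100 for Tau95, small nuclear and nucleolar RNA genes at 0.72 for Brf1 and glycolytic genes at 99.2 for Bdp1 and, weaker, at 1.27 for Tau95.

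Counts follow the limit by construction. At 1.5-fold, Pol III features lower and higher numbered 49 and 9 for Bdp1, 136 and 17 for Brf1, 92 and 18 for C160, and 12 and 73 for Tau95. Other features numbered 417 and 449, 931 and 827, 446 and 845, and 502 and 1340. At the 1st and 99th percentiles of other features, Pol III features above the limit numbered 40, 34, 29 and 15 at 0 min and 33, 15, 14 and 26 at 30 min. For the change they numbered 6 down for Bdp1, 39 down and 2 up for Brf1, 2 up for C160 and 6 up for Tau95. Other features past these limits numbered 56, 57, 58, 60 or 61. Only counts that moved are listed. The Pol III counts down for C160, up for Bdp1 and down for Tau95 stayed within the factor allowed. Among features with a mean value above 2, those higher by 2-fold were 0 for Bdp1, 2 for C160 and 18 for Tau95.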

Other observations

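The tests of chance, missing TFIIIB, level and the count for the tag in this part were fixed before their results, and those of the tag by difference, of the shared background and of the same measure on the other proteins after. All features in this part outside the naming rule were chosen after their values were seen. A set of regions with no tRNA gene beside them had higher values for Tau95 than for the other proteins. Between RPB5 and CNS1, the value of Tau95 exceeded the mean of Bdp1, Brf1 and C160 by 3.56 at 0 min and 2.65 at 30 min. The excess was 2.67 and 2.83 between PPM2 and ARG8, 3.08 and 2.45 between TLG1 and SDC1, and 2.97 and 2.44 between GUP1 and SCY1. Between ADE8 and SIZ1 it was 2.59 and 1.73. Between TFC6, itself a gene of a TFIIIC subunit, and ESC2 it was 2.49 and 1.57. Those beside ADE8 and TFC6 are known in yeast as sites of TFIIIC without polymerase.

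An excess of 1 or more at both times was found at 31 of 4786 features away from Pol III genes, and the highest of 1000 shuffles of the 30 min values was 18, which speaks against chance scatter as the whole cause. Such an excess is not particular to Tau95: by the same measure Bdp1 had 59 features (highest of shuffles 15), Brf1 5 (5) and C160 4 (3). The spread of other features at 0 and 30 min was 1.35 and 1.39 for Bdp1 and 1.30 and 1.16 for Tau95. It was 1.00 and 1.27 for Brf1 and 1.03 and 1.11 for C160. A fixed limit may be passed more often where the spread is wider, so these counts do not rank the proteins. The largest excess held at both times was 2.67 for Tau95, 1.81 for Bdp1, 1.38 for Brf1 and 1.04 for C160. For the epitope tag, the test fixed beforehand did not decide: 12 of the 31 passed the limit against both Bdp1 and Brf1 at both times, between its 2 bounds. A tag effect would raise the myc-tagged Bdp1 and Brf1 above the HA-tagged C160 as well, but how far they stood above it depended on how the features were chosen. At the 31 features, chosen in part for low Bdp1 and Brf1, the median of their mean minus C160 was -0.17 at 0 min and -0.15 at 30 min. At 39 features chosen by an excess of Tau95 over C160 alone, 17 of them among the 31, it was 0.38 (95% interval 0.20 to 0.53) and 0.32 (0.01 to 0.62). These intervals cross the bound of 0.5, which was set after the first of these values were seen, so a part played by the tag stays open. At the 39 features the median of Tau95 minus C160 was 1.37 at 0 min and 1.38 at 30 min. That of Tau95 minus the mean of Bdp1 and Brf1, which carry the same tag, was 0.98 and 1.07. These features were chosen for high Tau95, which by itself favours a gap to Bdp1 and Brf1. The values therefore do not decide whether the tag is the whole cause. The median values of Bdp1, Brf1 and C160 at the 31 features stood no higher than percentile 56.5 of other features, where that of Tau95 stood at 86.4. TFIIIC present without TFIIIB and polymerase stays open as a hypothesis, because the features chosen by the excess of any of the other proteins also stood below percentile 90 for the rest, at 80.9 for Bdp1, 58.1 for Brf1 and 88.8 for C160.

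A separate pattern for Tau95 concerns ribosomal protein genes, whose median went from 0.28 at 0 min (98.1st percentile of random lists) to 0.09 at 30 min (42.3rd). Relative to other features the change was -0.41, and 100 of 127 features were below the median change of other features. It was -0.47 at features upstream of the gene (n = 61) and -0.36 at those downstream (n = 66). Glycolytic and other highly transcribed genes had -0.38 relative to other features, with -0.40 upstream (n = 15) and -0.05 downstream (n = 11). Lower Tau95 values were thus not seen at ribosomal protein genes alone. The glycolytic list stood less far out against lists matched on the value at 0 min, and the lists were not tested against each other. Ribosome biogenesis genes had 0.09. A dependence on level would show in level-matched lists, but the ribosomal protein median was below theirs by -0.38 and below the lowest of 10000. A background shared by all myc immunoprecipitations would lower Brf1 too, where the difference was 0.0024. Bdp1 did go the same way, by -0.11 (76 of 121 features below) and by -0.25 at downstream features (45 of 59), as did the HA-tagged C160 by -0.11, so a background in part of the immunoprecipitations stays open. Repression of these genes by rapamycin, as a loss of signal tied to Pol II transcription, was not tested and stays open as well. Ribosome biogenesis genes, which rapamycin also represses, did not share the lower values. Their Tau95 median at 0 min was -0.33 (5.08th percentile), so they had no raised signal to lose and cannot decide this.

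Of the 50 other features with the lowest change, 25 lay to the left of a Pol III gene for Brf1 and 25 for C160, against 4.33% of all other features, and 5 did for Bdp1 and 2 for Tau95. Of the 50 with the highest change, 4 did for Brf1, 2 for C160, 3 for Bdp1 and 6 for Tau95. The regions left of RDN5-5 and RDN5-6, 5S gene copies outside the main array, had changes of 1.23 and 1.14 for C160 and of 1.58 and 1.14 for Tau95, unlike the tRNA genes for C160. Between SOK1 and TRP1 the value was 1.52 and 2.10 on the C160 arrays, 0.36 and 1.94 on those of Brf1, -0.18 and 0.37 on those of Bdp1 and 0.01 and 0.96 on those of Tau95.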
